A study of Mus musculus with 2 samples.

How the data were processed

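The samples were E12 mouse telencephalic tissue of the C57BL/6 background, 1 sample of H2AZ cKO and 1 of floxed control. The tissue label reads telencephalon while the extraction protocol speaks of cerebral cortex, so how much ventral tissue was taken is open. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 2 ug of total RNA with an Illumina TruSeq RNA kit. The series text speaks of triplicates, but the deposited table holds 1 count column per genotype, and whether it pools replicates or is 1 of them is not given in the sources used here. The control column is headed WT per the file headers and was taken as the floxed control, the only other genotype of the series.

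Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 and the mouse build mm9 were involved, with no role or order given. The gene positions in the deposited table instead match GRCm38: 99.5% overlap the same gene in GENCODE M21 and 78.7% are identical. Whether counting used strand, and how reads with several matches were treated, is not given in the sources used here. The deposited read counts are whole numbers per Ensembl gene for 19202 genes, and the smallest count summed over both libraries is 2. The deposited CPM columns equal the counts times a constant per library, with all values within 0.01 of a whole number of reads, except that a count of 0 is written as 0.5 read. Their denominators, 8842436 and 8894180, exceed the sums of the rows by 2596 and 2982 counts. The authors' fold change is the ratio of these CPM values, and the authors' log2 fold change is its log2. The authors' p-value and adjusted p-value come from a comparison of 1 column with 1 column by a test that is not given in the sources used here. The authors' column of significance equals an adjusted p under 0.05 together with an absolute log2 of at least 1. Gene symbols were matched by identifier for 19112 genes and 90 kept their identifier.

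The counts summed to 8839840 in the H2AZ cKO and 8891198 in the floxed control. A count of 0 allows up to 0.339 and 0.337 CPM, the level of 3 counts, before the TMM scaling that the folds below use. The 10 most abundant genes took 4.48% and 4.12% of counts, and mitochondrially encoded genes 3.01% and 2.64%. Libraries were scaled with TMM factors of 0.986 and 1.01 from edgeR 4.0.16 in R 4.3.3, and DESeq2 1.42.0 in R gave the size factors of an alternative. The remaining steps were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The log2 ratio is H2AZ cKO over floxed control on log2(CPM + 1), for 14586 genes whose higher library reached 1 CPM. With 1 count column per genotype no test of the genotype was run and no p-value computed. Each ratio has an exact binomial (Clopper-Pearson) interval at 95% from its counts, which covers counting error only, since reads without molecular identifiers are not independent molecules. A fold against a count of 0 sets that count at 3 and leaves out the counting error of the other library, so the counting interval can allow a smaller fold.

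The 50 gene lists were fixed before the data were examined. A list's median log2 ratio was placed among 10000 random lists of the same size, drawn from 20 bins of mean level, where at least 5 members were tested. A trend on mature transcript length, GC content and level, taken from GENCODE M21 and the counts, was removed as an alternative, with all 3 fitted together, so their shares are not separated. Data simulated at these depths (14706 genes) held counting noise only, and the changed genes were drawn from those at 5 CPM or more. Of these, 95.5% of genes changed 2.5-fold or to 0.4 and 100% of those changed 4-fold or to 0.25 passed 2-fold. Changed genes under 5 CPM were not simulated. Of 100 unchanged lists, 5 lay outside the central 95%. The counting interval was checked on a subset of the genes and held the true ratio for 95.5% of them.

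Genes are named by a rule fixed before the data were examined: H2afz, H2afv, Setd2 and Nkx2-4; the 12 with the largest log2 ratio in each direction at 5 CPM or more and 50 summed counts or more, leaving out predicted Gm and Rik genes, pseudogenes and ribosomal RNA; in each list described, up to 4 members with the largest absolute log2 ratio, or all members in lists of 7 or fewer; and Pax6, Sox2, Eomes, Tubb3, Tbr1 and Neurod1. The values of a few single genes are not reported here, while medians and counts of their lists include them. Some named genes overlap another gene on the opposite strand, among them Hes5, Notch1, Shh, Gli1, Srcap, Otx2, Reln and Lhx5, and Neurod1 overlaps Cerkl on its own strand. The alternatives were pseudocounts of 0.1 and 5 CPM, no level floor and a floor of 5 CPM, scaling by total count or by DESeq2 size factors, the CPM as deposited, sizes of 1.5-fold and 4-fold, and, chosen after seeing the data, leaving out the X and Y chromosomes, protein-coding genes alone, and removal of the length, GC and level trend.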

Results

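RNA sequencing compared the telencephalon of mouse embryos at embryonic day 12 between a conditional knockout of H2AZ (H2AZ cKO) and a floxed control, whose allele can be deleted but was not. H2A.Z is a variant of histone H2A that in the mouse is encoded by H2afz and H2afv. At this stage the telencephalic wall holds dividing neural progenitors and early neurons. The data were 1 column of read counts per genotype, called a library here, over 19202 genes. The columns summed to 8839840 counts in the H2AZ cKO and 8891198 in the floxed control. There were no replicate columns, so none of the differences has a replicate check. Ratios are H2AZ cKO over floxed control after scaling of the libraries, with exact 95% binomial (Clopper-Pearson) intervals from the counts, which cover counting error only. Log2 ratios are on the log2(CPM + 1) scale, which understates the difference of genes at low counts.

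The first comparison asked how far the targeted gene was reduced, and how its paralog and Setd2, the H3K36 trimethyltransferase named in the series title, compared between the genotypes. H2afz was lower in the H2AZ cKO, at 191 CPM against 289 CPM (1664 and 2605 counts), a ratio of 0.661 (0.621 to 0.703). H2afv was higher, at 316 CPM against 252 CPM, a ratio of 1.25 (1.19 to 1.33), and its log2 ratio of 0.33 was 0.19 once the joint trend of the ratio with transcript length, GC content and level was removed. The other tested H2A variant genes were also above the control: the ratio was 1.21 for H2afx (1.15 to 1.27), 1.15 for H2afy (1.10 to 1.20), 1.11 for H2afy2 (1.05 to 1.18) and 1.17 for H2afj (0.999 to 1.36). The 6 tested variant genes had a median log2 ratio of 0.21, at the 99.3rd percentile of 10000 random gene lists matched on level, and of 0.12 (99.2nd percentile) with that joint trend removed. Setd2 stood at 133 CPM against 149 CPM, a ratio of 0.894 (0.826 to 0.968), or a log2 ratio of -0.16. With that joint trend removed the log2 ratio of Setd2 was -0.10. H2afz (ENSMUSG00000037894) lies on chromosome 3 at 137864487 to 137866922 in the deposited positions, which match GRCm38, H2afv (ENSMUSG00000041126) on chromosome 11 at 6427229 to 6444443, and Setd2 (ENSMUSG00000044791) on chromosome 9 at 110532597 to 110618633. The counts cover whole genes and the deleted exons of H2afz are not given in the sources used here, so the count does not measure the deleted part alone. The Cre driver is not given there either, so which cells of the tissue carry the deletion is open.

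Genes of the histone machinery around H2A.Z and H3K36 differed little. Of 20 tested genes for H2A.Z deposition and removal, 13 were above 0 on the log2 scale and 7 below, with a median log2 ratio of 0.13 at the 99.8th percentile. Srcap and Ep400, the ATPases of the complexes that load H2A.Z, were lower, at ratios of 0.715 (0.513 to 0.992) and 0.80 (0.747 to 0.856), while the subunits Yeats4 and Actr6 stood at 1.22 (1.14 to 1.31) and 1.21 (0.989 to 1.48). That median lay within the random range (0.03, 88.8th percentile) once the joint trend with length, GC content and level was removed. Among 24 writers, erasers and readers of H3K36 methylation the median log2 ratio was -0.05, at the 2.99th percentile and inside the central 95% of random lists. Within it Ash1l was at a ratio of 0.790 (0.712 to 0.877), Dnmt3a at 0.796 (0.738 to 0.859), Phf19 at 1.35 (0.991 to 1.85) and Setmar at 1.31 (0.899 to 1.93). The 18 Polycomb genes had a median of 0.02 (47.7th percentile). Percentiles of list medians are a description of these libraries and not a test of the genotype.

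Across all genes the libraries were close. Of 14586 genes that reached 1 CPM in the higher library, 13864 (95.1%) lay within 1.5-fold of each other, and Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.991. At least 2-fold higher in the H2AZ cKO were 22 genes and at least 2-fold lower were 70. The counting interval lay wholly beyond 2-fold for 7 of the higher and 20 of the lower genes. At the 1.5-fold size the counts were 280 higher and 442 lower. Among genes drawn with no change at these depths, 10 of 14506 passed 2-fold by counting noise. That draw held no differences between embryos, dissections or library preparations, so 10 is not the number of false calls among the 22 and 70. The 2-fold counts depend on the pseudocount and the floor: with 0.1 CPM in place of 1 CPM they were 188 and 296, with 5 CPM 3 and 9, and with a level floor of 5 CPM 7 and 33.

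**Figure D1:**
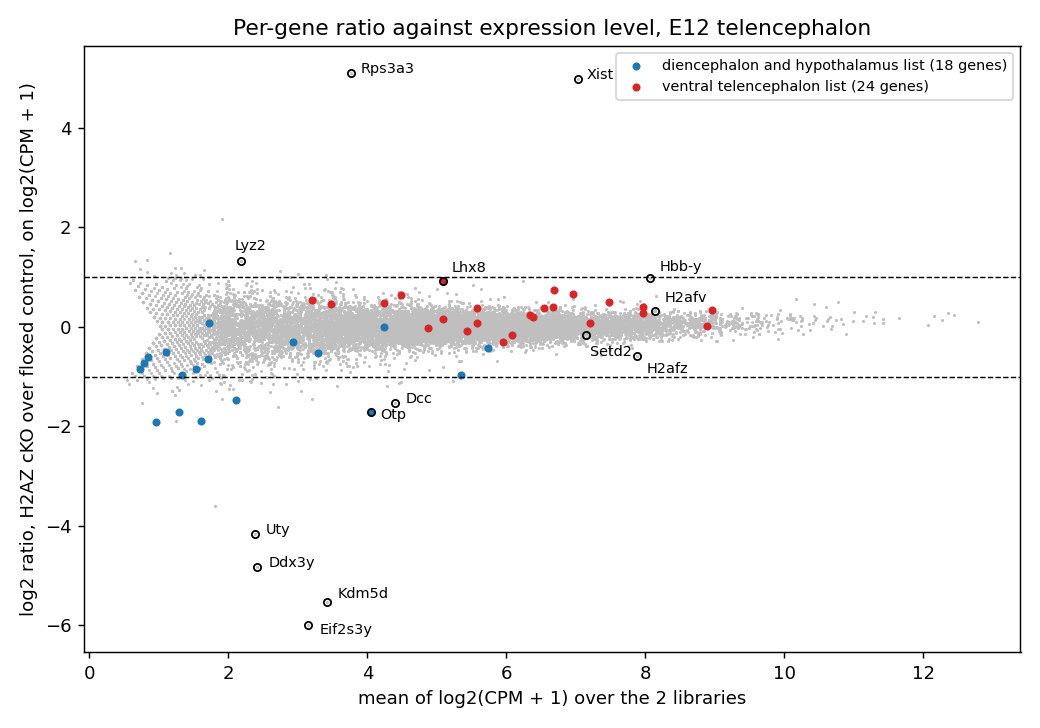
Each gray point is 1 of 14586 genes, with the mean of log2(CPM + 1) over both libraries on the x axis and the log2 ratio of H2AZ cKO over floxed control on the y axis; dashed lines mark 2-fold. Xist and the Y-linked genes lie farthest from 0 together with Rps3a3, the diencephalon and hypothalamus list (blue) lies mostly below 0 and the ventral telencephalon list (red) mostly above, with H2afz at -0.60.

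Sex-linked transcripts and the pseudogene Rps3a3 (685 and 12 counts) lay farthest apart between the libraries. Xist, the X-inactivation transcript, was at 732 CPM in the H2AZ cKO and 22.2 CPM in the floxed control, a ratio of 33.0 (28.7 to 38.2). The Y-linked genes Kdm5d (5 and 647 counts), Eif2s3y (1 and 630), Ddx3y (0 and 249) and Uty (2 and 190) were near 0 in the H2AZ cKO. Ddx3y was 80.2-fold lower with the H2AZ cKO set at the level of 3 counts. The counting interval of its ratio reached up to 0.0154, which allows 64.8-fold. The ratio of Eif2s3y was 0.00164 (4.15e-05 to 0.00918). Summed, the 4 Y-linked genes of the H2AZ cKO stood at 0.482% (0.208 to 0.953) of the floxed control. The 5 tested genes of the sex-linked list had a median log2 ratio of -4.84. Leaving out the X and Y chromosomes left 20 genes at least 2-fold higher and 61 lower.

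Beyond the sex-linked genes, the lower genes chosen by size and level were Otp, Shox2, Sim1, Dcc, Lnpep, Zfp382, Arid5b and Zbtb37. Otp, a homeobox gene of the hypothalamus, was at 71 counts against 262, a ratio of 0.280 (0.213 to 0.366). Shox2 was at 24 against 95 (0.261, 0.160 to 0.412), Sim1 at 14 against 56 (0.259, 0.133 to 0.471) and the netrin receptor Dcc at 99 against 315 (0.325, 0.257 to 0.409). Lnpep, Zfp382, Arid5b and Zbtb37 followed, at ratios of 0.336 (0.205 to 0.533), 0.308 (0.157 to 0.569), 0.317 (0.165 to 0.574) and 0.402 (0.292 to 0.546). Shox2 and Zbtb37 overlap Rsrc1 and Serpinc1 on the opposite strand, and reads of such pairs cannot be told apart without strand.

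On the higher side the lysozyme gene Lyz2 was at 54 counts against 17, a ratio of 3.29 (1.88 to 6.05). Mir6236 stood at 2.49 (1.63 to 3.89), Fam131c at 2.32 (1.59 to 3.44), Cdh20 and Coch each at 2.19 (1.44 to 3.40), Man1a at 2.15 (1.32 to 3.57) and the homeobox gene Nkx2-3 at 2.09 (1.52 to 2.89). Lhx8, a LIM homeobox gene of the ventral forebrain, was at 45.8 CPM against 23.7 CPM (1.93, 1.63 to 2.29), and the noncoding transcript AI606473 beside it on chromosome 3 at 2.21 (1.61 to 3.08). The globin genes Hbb-y and Hbb-bs were at 1.99 (1.87 to 2.11) and 1.90 (1.70 to 2.13). Of the 22 genes at least 2-fold higher, 12 were protein-coding and 5 pseudogenes (Rps3a3, Gm13529, Gm8524, Gm11249 and Gm11989, named because the count is small and chosen after their values were seen).

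Among the fixed regional lists, that of the diencephalon and hypothalamus was lower and that of the ventral telencephalon higher. Genes of dorsal telencephalic patterning lay inside the random range. Of 18 tested genes of the diencephalon and hypothalamus, 17 were below 0 and 12 at least 1.5-fold lower, and none was 1.5-fold higher. Their median log2 ratio was -0.79 (counting interval -1.03 to -0.56), below all 10000 random lists, whose central 95% ran from -0.23 to 0.17. Nkx2-4, a homeobox gene of the hypothalamus on chromosome 2 at 147083316 to 147085445, had 0 counts against 25. It was 8.06-fold lower with the H2AZ cKO set at the level of 3 counts. The counting interval of its ratio reached up to 0.164, which allows 6.08-fold. Nkx2-2 had 5 counts against 44 (ratio 0.118, 0.0364 to 0.296), and Nr5a1, a nuclear receptor of the ventromedial hypothalamus, 3 against 31 (0.10, 0.0196 to 0.321). Most of these genes had under 50 counts in each library, and the median moved with the pseudocount, to -1.25 with 0.1 CPM and -0.37 with 5 CPM, each time below the central 95% of random lists. Nkx2-4 is the lowest member, so setting it at 3 counts cannot move the median.

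Genes of the fixed list of the ventral telencephalon and the GABAergic lineage were higher. Of 24 tested genes 20 were above 0, 16 with an interval above 1, and 4 reached 1.5-fold: Lhx8, Sst at 1.67 (1.52 to 1.83), Npy at 1.59 (1.29 to 1.96) and Nkx2-1, the determinant of the medial ganglionic eminence, at 155 CPM against 97.9 CPM (1.58, 1.45 to 1.73). The median log2 ratio was 0.35 (counting interval 0.25 to 0.37), above all random lists, and between 0.28 and 0.35 in every setting tried. A second list of 13 genes of the medial ganglionic eminence and its interneurons, written after the data were seen, had a median of -0.00502 (48.9th percentile), with 5 genes above 0 and 8 below. The 14 genes of dorsal telencephalic patterning had a median of 0.08 (84.5th percentile), with Dmrta2 at 1.27 (1.15 to 1.41), Lmo3 at 1.17 (1.07 to 1.27), Neurog1 at 1.16 (0.962 to 1.41) and Dmrt3 at 0.821 (0.672 to 1.0). The cortical hem and dorsal midline had a median of -0.27 over 9 genes (3.73rd percentile), and the choroid plexus -0.37 over 6 genes (1.49th percentile). In the choroid plexus list Ttr had 9 counts against 28 (0.333, 0.138 to 0.725), Lmx1a 7 against 16 (0.453, 0.157 to 1.16) and Otx2 118 against 157 (0.778, 0.607 to 0.994), while Foxj1 stood at 1.05 (0.842 to 1.30), Enpp2 at 0.724 (0.476 to 1.09) and Msx1 at 0.658 (0.216 to 1.86).

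**Figure D2:**
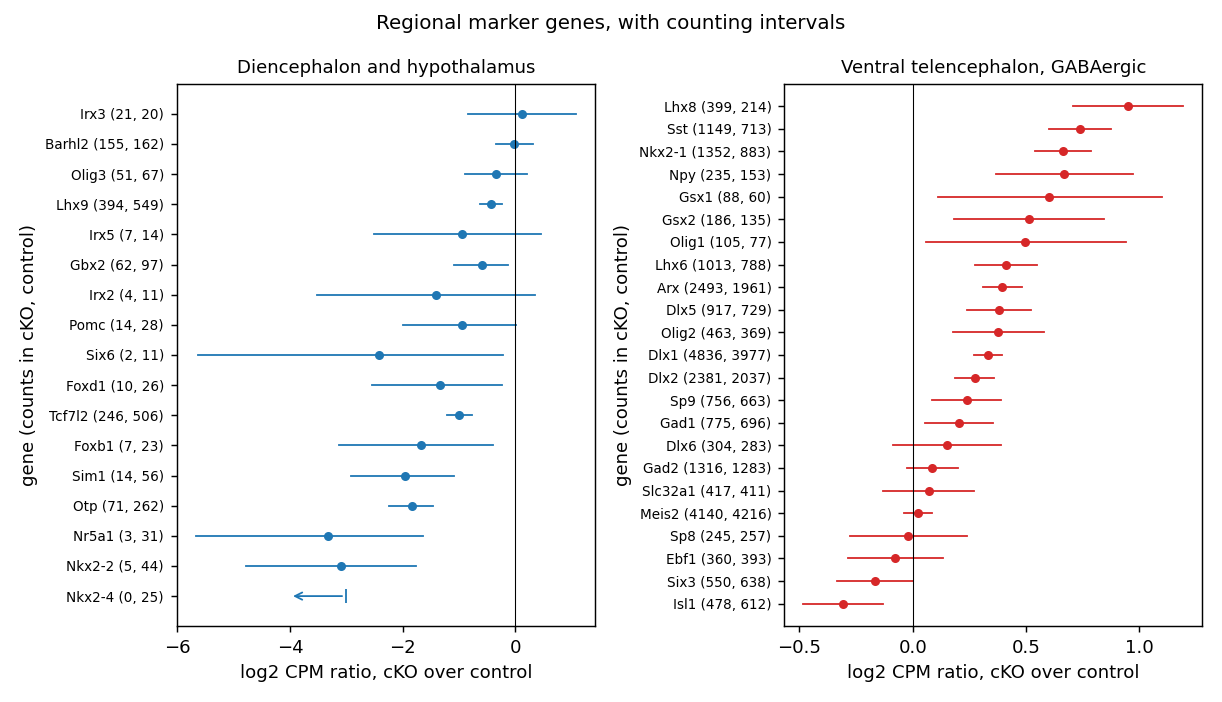
Log2 CPM ratio of H2AZ cKO over floxed control (x axis, no pseudocount) for 17 of the 18 diencephalon and hypothalamus genes (left) and 23 of the 24 ventral telencephalon genes (right), with counts in the H2AZ cKO and the control beside each name. Points are ratios, bars exact 95% counting intervals, and the arrow starts at the value of Nkx2-4 set at 3 counts. Most intervals lie left of 0 on the left and right of 0 on the right, with Lhx8 at the top and Isl1 (478 and 612 counts) at the bottom of the ventral list.

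Markers of the progenitor to neuron sequence lay near 1. Pax6 was at a ratio of 0.972 (0.898 to 1.05), Sox2 at 1.06 (1.0 to 1.12), Eomes at 0.982 (0.931 to 1.04), Tbr1 at 1.02 (0.970 to 1.07), Neurod1 at 1.07 (0.965 to 1.19) and Tubb3 at 1.08 (1.06 to 1.10). With the length, GC and level trend removed the log2 ratios of Sox2 and Tubb3 turned to -0.0227 and -0.0746. The median log2 ratio was 0.07 for 24 apical progenitor genes (89.5th percentile), 0.09 for 14 intermediate progenitor genes (93.5th percentile) and 0.05 for 26 genes of postmitotic neurons (48.2nd percentile), all inside the central 95% of random lists. Among the apical progenitor genes the Notch effectors Hes5 and Hes1 were at 1.62 (1.37 to 1.91) and 1.34 (1.16 to 1.54), Phgdh at 1.21 (1.11 to 1.33) and Notch1 at 0.793 (0.735 to 0.855). Of the intermediate progenitor genes Hes6 stood at 1.21 (1.13 to 1.30), Sstr2 at 1.12 (1.02 to 1.24) and Neurod4 at 0.837 (0.576 to 1.21). Among the neuronal genes Myt1l was at 0.807 (0.735 to 0.885), Gap43 at 1.14 (1.08 to 1.19), Stmn3 at 1.14 (1.09 to 1.20) and Syt4 at 1.15 (1.05 to 1.27). Cajal-Retzius cell genes had a median of -0.18 over 9 genes (0.97th percentile), with Lhx1 at 0.669 (0.493 to 0.902), Lhx5 at 0.685 (0.550 to 0.851), Ebf3 at 0.749 (0.623 to 0.90) and Reln at 0.879 (0.821 to 0.941). Without the joint trend with length, GC content and level that median was -0.07 and within the random range.

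Cell cycle genes were slightly higher. Of 39 genes of the G1/S phase 33 were above 0, with a median log2 ratio of 0.15, and of 44 genes of the G2/M phase 36 were above 0, with a median of 0.13, both above all random lists. None reached 1.5-fold. Ung was at 1.31 (1.12 to 1.53), Tipin at 1.28 (1.15 to 1.42), and Ccnd1 and Slbp each at 1.27 (1.16 to 1.39 and 1.15 to 1.41). In the G2/M list Cdk1 was at 1.32 (1.21 to 1.43), Cks1b at 1.27 (1.14 to 1.41), Hmgb2 at 1.25 (1.20 to 1.31) and Birc5 at 1.23 (1.12 to 1.35). Of 7 cyclin-dependent kinase inhibitors 5 were tested (median 0.13, 91.6th percentile): Cdkn1a at 1.04 (0.815 to 1.33), Cdkn1b and Cdkn1c at 1.09 (1.02 to 1.17 and 1.02 to 1.18), Cdkn2c at 1.24 (1.06 to 1.45) and Cdkn2d at 1.18 (1.02 to 1.36). The p53 target and apoptosis list had a median of 0.18 over 19 genes (99.9th percentile), with Phlda3 at 1.48 (0.956 to 2.32), Tnfrsf10b at 1.55 (0.652 to 3.86) and Eda2r at 0.609 (0.249 to 1.41). Replication-dependent histone genes had a median of 0.02 over 8 genes (61.0th percentile).

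Signalling lists differed in direction. Of 12 Sonic hedgehog pathway genes 10 were below 0, with a median of -0.17 (0.28th percentile): the targets Gli1 and Ptch1 stood at 0.711 (0.527 to 0.955) and 0.821 (0.705 to 0.956), Sufu at 0.814 (0.725 to 0.913), and the ligand gene Shh itself was higher, at 62 counts against 35 (1.83, 1.19 to 2.86). The 13 BMP genes had a median of 0.11 (92.2nd percentile), with Grem1 at 2.45 (1.17 to 5.48), Id1 at 1.76 (1.32 to 2.36), Nog at 1.41 (1.12 to 1.79) and Id3 at 1.33 (1.02 to 1.73). For 19 Notch genes the median was 0.09 (96.2nd percentile), with Jag2 at 1.29 (1.09 to 1.51), and for 19 Wnt genes -0.05 (13.6th percentile), with Fzd5 at 0.569 (0.322 to 0.981), Wnt3 at 0.609 (0.332 to 1.09), Tcf7 at 0.808 (0.561 to 1.16) and Sfrp2 at 1.27 (1.09 to 1.49). Once the joint trend with length, GC content and level was removed BMP (98.9th percentile) and Notch (98.0th) lay above and Wnt (2.42nd) below the central range. BMP also lay above it with a pseudocount of 0.1 (0.19, 98.7th percentile). The 27 axon guidance genes had a median of -0.06 (1.39th percentile), with Dcc and Unc5c (0.639, 0.476 to 0.852) lower by at least 1.5-fold, Efna5 at 0.723 (0.574 to 0.907) and Slit2 at 0.779 (0.664 to 0.914), and were within the random range without that joint trend (-0.01, 41.6th percentile) or without the X and Y chromosomes. The 21 synaptic and excitability genes had a median of -0.02 (21st percentile).

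Markers of blood and macrophages were higher in the H2AZ cKO. In the erythroid list 5 of 9 genes were at least 1.5-fold higher, with a median log2 ratio of 0.75 above all random lists: Hbb-bh1 was at 2.76 (1.38 to 5.88), Hbb-y at 1.99, Hba-a1 at 1.82 (1.58 to 2.11), Hba-a2 at 1.76 (1.45 to 2.14) and Hba-x, chosen after its value was seen, at 1.71 (1.49 to 1.96). Reads of the near-identical globin copies can be split between them. The microglia and macrophage list had a median of 0.37 over 14 genes, at the 99.97th percentile, with Lyz2 at 3.29, Tyrobp at 2.73 (1.32 to 6.05), Trem2 at 1.98 (0.910 to 4.54) and C1qa at 1.54 (1.02 to 2.35). Endothelial genes (median -0.08 over 17, 18.1st percentile), pericyte genes (0.01 over 6, 56.1st), astrocyte and oligodendrocyte lineage genes (0.03 over 10, 69.5th) and neural crest genes (0.09 over 5, 71.2nd) lay inside the random range. Meninges and mesenchyme genes had a median of -0.23 over 11 genes (3.05th percentile). It went to -0.36 (0.86th) with a pseudocount of 0.1 and to 0.24 (98.1st) with a floor of 5 CPM, both outside the random range, was 0.00497 (59.9th) with no floor, and lay at the 2.24th percentile among protein-coding genes alone. Lists of other tissues had fewer than 5 genes at 1 CPM: 2 for surface ectoderm and olfactory epithelium, 1 each for midbrain and hindbrain, skeletal muscle, germline and olfactory receptors, and 0 of 39 Hox genes.

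**Figure D3:**
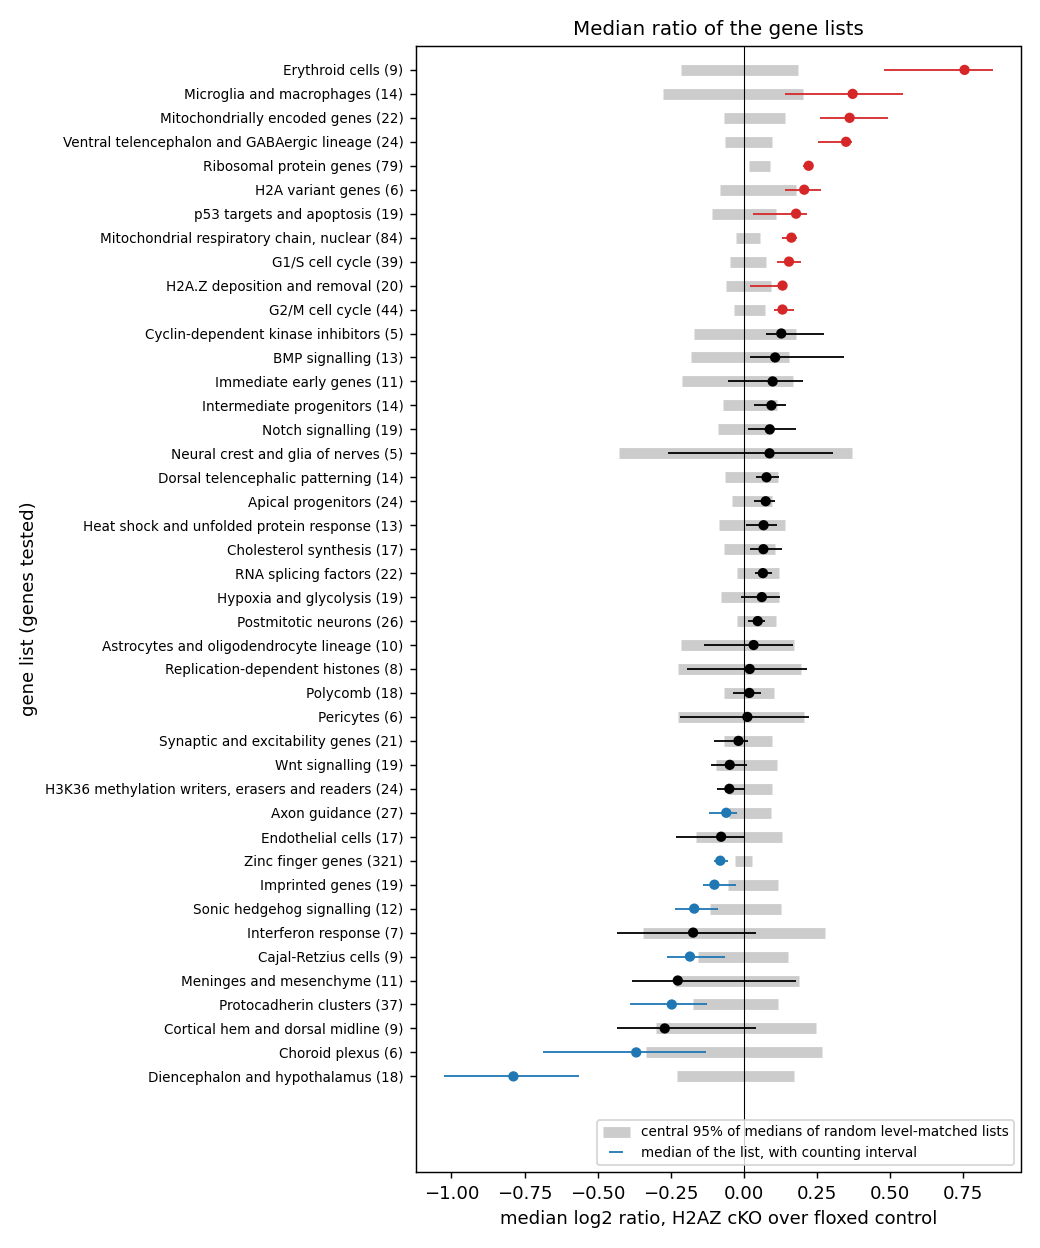
Median log2 ratio of H2AZ cKO over floxed control (x axis) for each gene list with at least 5 tested genes except the sex-linked list, with the number of tested genes in parentheses; lines are counting intervals of the median, gray bars the central 95% of medians of random lists matched on level, and red and blue mark medians above and below them. The diencephalon and hypothalamus list at -0.79 and the erythroid list at 0.75 lie at the ends.

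Zinc finger genes were slightly lower as a class. Of 321 tested, 212 were below 0 and 17 at least 1.5-fold lower, with a median log2 ratio of -0.08, below all random lists. Zfp382, Zfp445, Zfp677 and Zfp971 were at ratios of 0.308, 0.449 (0.360 to 0.556), 0.381 (0.219 to 0.639) and 0.296 (0.116 to 0.666). Clustered protocadherin genes, cell-surface adhesion proteins of neurons, had a median of -0.25 over 37 genes (0.24th percentile), 27 of them below 0 and 6 at least 1.5-fold lower, and a median of -0.15 (1.93rd percentile) without the joint trend with length, GC content and level. Pcdhgb8, Pcdhgb4, Pcdhga4 and Pcdhb11 were at 0.302 (0.110 to 0.722), 0.546 (0.296 to 0.977), 0.572 (0.340 to 0.943) and 0.453 (0.157 to 1.16), and the genes of the gamma cluster share exons, so their counts are uncertain. The 19 imprinted genes had a median of -0.10 (0.18th percentile), with Dlk1 at 0.685 (0.623 to 0.751), Peg3 at 0.701 (0.649 to 0.756), Magel2 at 0.786 (0.712 to 0.868) and Zim1 at 0.801 (0.553 to 1.16). Without that joint trend the imprinted median was -0.04, inside the random range.

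Genes of translation and respiration were higher by a small amount. Of 79 genes of the ribosomal protein list, which was matched by name and holds the pseudogenes Rps3a3 and Rps4l, 76 were above 0, with a median log2 ratio of 0.22. Of 84 nuclear genes of the respiratory chain 77 were above 0, with a median of 0.16. The 22 mitochondrially encoded genes had a median of 0.36, 21 of them above 0. All 3 medians lay above all random lists. Rps21 was at 1.41 (1.32 to 1.5), Rps19 at 1.37 (1.29 to 1.45) and Rpl23a at 1.49 (1.37 to 1.62). Ndufa4l2 was at 1.64 (1.01 to 2.71), Ndufaf6 at 1.45 (1.03 to 2.05), Ndufb4 at 1.40 (1.15 to 1.69), Atp5s at 1.36 (0.969 to 1.91) and mt-Nd3 at 1.71 (1.26 to 2.34). The transfer RNAs mt-Ty, mt-Tn and mt-Tc were at 3.0 (1.42 to 6.9), 2.87 (1.3 to 7.0) and 2.37 (1.31 to 4.47). Their counts were few, at 29 and 10, 25 and 9, and 39 and 17. These genes lie side by side on the same strand, between positions 5089 and 5326, so they need not be separate differences. Summed, mitochondrially encoded genes took 3.01% of counts in the H2AZ cKO and 2.64% in the floxed control. The processed pseudogene Rps3a3 had 685 counts against 12, while its parent Rps3a1 had 2708 against 3191. Short transcripts were higher in the H2AZ cKO in general: the median log2 ratio was 0.12 in the tenth of genes with the shortest mature transcripts (median 971 nt) and -0.11 in the tenth with the longest (median 8386 nt). With the joint trend of length, GC content and level removed, the medians were 0.07 for ribosomal proteins, 0.03 for the nuclear respiratory chain, 0.20 for mitochondrially encoded genes, 0.12 for G1/S and 0.08 for G2/M genes, each above the central 95% of random lists.

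**Figure D4:**
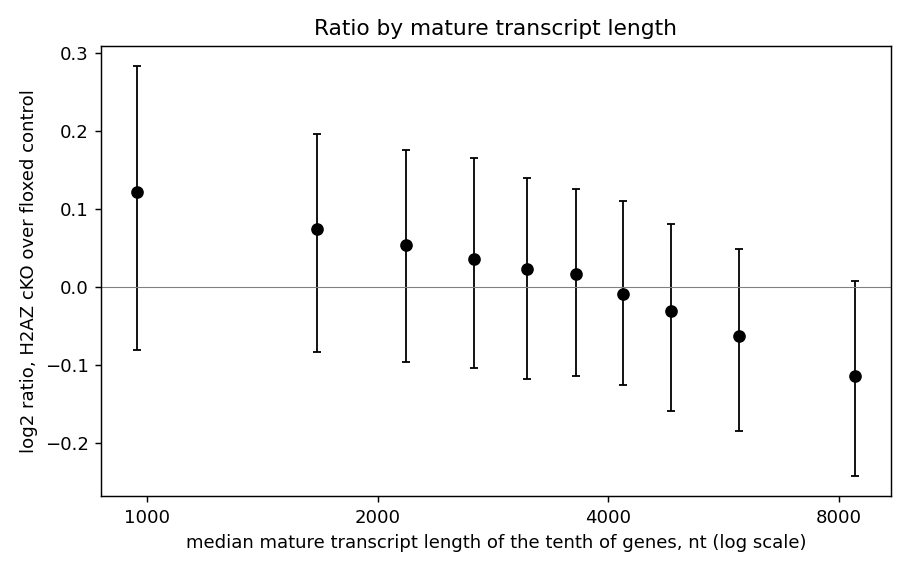
Log2 ratio of H2AZ cKO over floxed control (y axis) by mature transcript length in nt (x axis, log scale), for the tested genes cut into 10 bins by length; points are medians and bars run from the lower to the upper quartile of genes. Medians go from 0.12 at 971 nt to -0.11 at 8386 nt.

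The remaining lists lay inside the central 95% of random lists: hypoxia and glycolysis (median 0.06, 76.8th percentile), immediate early genes (0.10, 88.2nd), heat shock and unfolded protein response (0.07, 72.7th), interferon response (-0.17, 18.4th), cholesterol synthesis (0.07, 85.4th) and RNA splicing factors (0.07, 63.2nd). Of 44 lists with at least 5 tested genes, 11 lay above and 9 below the central range. Lists of independent genes would give 2.2 by chance. Some lists share genes, members of a list can vary together, and the sex-linked list is counted. The comparison therefore does not measure an excess over chance.

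In the authors' deposited table, 42 genes were marked significant and higher in the H2AZ cKO and 130 lower, at an adjusted p under 0.05 and at least 2-fold. The authors' deposited table gave H2afz a log2 fold change of -0.64, which is under that size, and marked Nkx2-4 as lower. All 92 genes at least 2-fold different here (22 higher and 70 lower) were among the 172 marked in the authors' deposited table. Both sets rest on the same 2 count columns, so the overlap is no separate check. The p-values of the authors' deposited table compare the reads of 2 libraries and not the genotypes. With the X and Y chromosomes left out, 38 higher and 116 lower genes were marked in the authors' deposited table.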

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

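Leaving out the X and Y chromosomes, protein-coding genes alone and removal of the length, GC and level trend were chosen after seeing the data. No paired analysis was possible because each genotype has 1 count column, and the alternatives that need replicate columns were not run for that reason. The counts of genes at least 2-fold higher and lower (22 and 70) became 188 and 296 with a pseudocount of 0.1, 3 (Xist, Rps3a3 and Gm13529) and 9 with a pseudocount of 5, 7 and 33 with a floor of 5 CPM, 280 and 442 at 1.5-fold, and 3 (the same as with the pseudocount of 5) and 5 (Kdm5d, Eif2s3y, Ddx3y, Uty and Gm29650) at 4-fold; these follow from how the settings treat low counts and size. With protein-coding genes alone 12 were higher. Total-count scaling gave 20 and 85, DESeq2 size factors 21 and 76, and the CPM as deposited 20 and 83. The diencephalon and hypothalamus median (-0.79) became -1.25 and -0.37 with pseudocounts of 0.1 and 5 and -0.54 with a floor of 5 CPM. With the length, GC and level trend removed, the log2 ratio of H2afz went from -0.60 to -0.75 and that of H2afv from 0.33 to 0.19, and the small ratios of Sox2 and Tubb3 reversed to -0.0227 and -0.0746; the cause was not tested further. In the authors' deposited table, an adjusted p under 0.01 with at least 2-fold left 16 higher and 69 lower genes. Setd2 and the ventral telencephalon median kept their direction under each alternative run. Of 20 lists outside the central range, 16 stayed outside with the trend removed. Depth limits the genes under about 50 counts, most of the diencephalic ones among them.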

Other observations

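The tests on the sex difference, the regional genes, the transcript-length trend and the chromosome 3 region were chosen after those patterns were seen, each with its prediction written before its own result; the terms of the table's gene annotation, the sum of Rps3a1 and Rps3a3 and the genes named below were likewise chosen after seeing the data.

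Beyond the fixed lists, 983 biological process terms of 15 to 200 genes in the deposited annotation were placed among random lists. The joint trend with transcript length, GC content and level was removed first. Above the central 95% lay 58 terms and below it 29, where 24.6 would by chance on each side. The number below is close to chance. The chance number takes genes and terms as independent, while terms share genes, so the 58 do not measure an excess. Medians given here are after removal of that trend, and counts of genes above or below 0 before it. Neuron fate commitment had the highest median of these terms, 0.32, with 12 of 15 genes above 0, and its higher members included Gbx1 (124 and 71 counts), Shh, Nkx2-1, Gsx1 (88 and 60) and Gsx2 (186 and 135), most of them also in the ventral telencephalon list. DNA replication initiation had 14 of 15 genes above 0 with a median of 0.14, led by Mcm7 (3230 and 2730) and Mcm3 (1688 and 1429). DNA integration and the establishment of integrated proviral latency lay below all 2000 random lists, with medians of -0.22 and -0.24. DNA integration had 28 of 35 genes below 0, mostly predicted genes such as Gm43305 (1682 and 2258) and Gm42860 (80 and 149). The sum of Rps3a1 and its pseudogene Rps3a3 was 3393 counts against 3203, a ratio of 1.10 (1.04 to 1.15), while Rps3a1 alone stood at 0.878 (0.834 to 0.924).

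The high Xist and near-absent Y-linked counts of the H2AZ cKO may come from embryos of different sex behind the libraries. X-linked genes known to escape inactivation should then be higher in the H2AZ cKO, and the median log2 ratio of 10 such genes was 0.28, above all random lists of other X-linked genes (central 95% -0.12 to 0.13). Kdm6a was at 1.40 (1.20 to 1.62), Eif2s3x at 1.28 (1.20 to 1.36) and Kdm5c at 1.27 (1.18 to 1.37), while Mid1 was at 0.775 (0.722 to 0.831). The floxed control held Xist at 3.03% (2.62 to 3.49) of the level in the H2AZ cKO, and the sexes are not given in the labels. If the embryos did differ in sex, sex and genotype coincide in this pair of libraries for every gene and list, not only for the sex-linked ones. The near-absent Y-linked counts, the high Xist and the median of the escape genes all go the way that embryos of different sex predict, Mid1 aside. A genotype effect on these genes could not be told apart from sex with 1 count column per genotype.

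The lower diencephalic and higher ventral telencephalic genes may come from where the tissue was dissected or from the genotype. The transcript-length trend is argued against as the whole cause, since the diencephalon and hypothalamus median was still -0.72 with the joint trend of length, GC content and level removed, below all random lists. A larger share of medial ganglionic eminence is argued against by a second list of 13 genes of that region and its interneurons, whose median was -0.00502 (resampled members -0.06 to 0.04) where the fixed ventral list had 0.35, although Zeb2, Sox6 and Cxcr4 of that list are also active elsewhere in the forebrain. A smaller share of diencephalic tissue in the H2AZ cKO piece stays open: a second list of 17 diencephalic genes had a median of -0.39 (0.06th percentile, 8 of 17 at least 1.5-fold lower), with Sox14 at 2 counts against 32. Those 8 had at most 50 counts in each library. Of the 17 genes 14 were below 0 and 3 above, Asb4 among the latter at 236 counts against 187 (interval of the ratio 1.07 to 1.59). The better-counted Prox1 (244 and 291) and Fezf1 (170 and 210) had intervals that included 1. The genotype stays open and untested too, as each genotype has 1 count column.

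The fall of the ratio with mature transcript length may reflect a difference in RNA integrity or fragment size. Its partial Spearman correlation across 14543 genes, given genomic span, GC content and level, was -0.25 (-0.26 to -0.23, resampled over genes, which are not independent replicates). GC content is argued against as the source, because the correlation stood at that size with GC content given. Slower transcription of long genes is argued against, because the partial correlation with genomic span, given mature length, GC content and level, was 0.0138 (-0.0036 to 0.0315). With none of these given, the correlation with genomic span was -0.14 (-0.16 to -0.12). RNA integrity was not measured in the sources used here, and a genotype effect on long transcripts stays open.

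Strain sequence carried around the floxed allele was tested by the share of genes at least 1.5-fold different within 10 Mb of H2afz, which was 6.58% (5 of 76, 2.17 to 14.7) against a median of 4.72% and an upper limit of the central 95% of 11.1% over 2391 windows, and so could not be decided at this number of genes. Dnajb14, Unc5c, Gm43254 and Gm26691 were among them. Dnajb14, which starts next to H2afz on chromosome 3 at 137867675, was at 151 counts against 266 (ratio 0.587, 0.478 to 0.720). The window with the highest share lay farther along chromosome 3, from 152000001 to its end, with 7 of 38 genes at least 1.5-fold different, Lhx8 and AI606473 among them. Windows at a chromosome end could run past it and so cover less sequence, and such windows also enter the 11.1% limit.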
